A study of Homo sapiens with 12 samples.

How the data were processed

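RNA from 12 sorted samples of human fetal brain was measured on 1-colour Illumina HT-12 v4 BeadChips. Per the labels, cells were sorted by flow cytometry into 4 populations by the surface antigens CD133 and CD140, total RNA was extracted right after sorting, and cDNA was amplified with a NuGEN kit and labelled with biotin. CD133 is the product of PROM1, and CD140a, the antigen named in the title of the series, is the product of PDGFRA. Each population had 3 replicates, lettered A, B and C in the labels, each from a separate donor per the labels.

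The deposited non-normalized table holds 47322 probes with an average bead signal, an intensity on a linear scale, for each array, and a detection p-value per the file headers. These deposited intensities had no value below 0 and array medians of 120.7 to 211.7, so background was taken as not subtracted, and they were not normalized between arrays. The scanner software version was not given in the sources used here. The authors also deposited a table of processed log2 values for 15584 probes, which had the same rank order within each array as the intensities. These were exactly the probes with a deposited detection p-value at or under 0.01 in at least 2 replicates of at least 1 population. Array medians of the authors' log2 values, in the order of replicates A, B and C, were 5.25, 5.59 and 5.19 in CD133-CD140-, 5.81, 5.76 and 5.32 in CD133-CD140+, 5.43, 5.69 and 5.70 in CD133+CD140-, and 5.38, 5.41 and 5.39 in CD133+CD140+, while array means ran from 5.95 to 6.01. The background, normalization and centring steps behind it stay unknown. Group differences in it were 1.50 to 1.58 times as large as those computed here, by regression across genes, with r of 0.962 to 0.985 across genes. It was used as an alternative.

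Intensities were corrected and normalized with neqc in limma 3.58.1 under R 4.3.3. This fits background with the normal-exponential model, with negative controls inferred from the detection p-values, adds an offset of 16, applies quantile normalization over all 47322 probes and takes log2. Gene names came from a platform annotation that covers the probes of the authors' table. In it 11524 probes had 1 gene symbol and none had several, while 4060 probes of the authors' table were unnamed here. The 31738 probes outside the authors' table were not analysed by gene here. Of the named probes, 11518 matched a current gene record by Entrez identifier, and 0 symbols changed. X- or Y-linked transcripts that differ by sex, 13 probes, were left out of every step that names genes. Probes with a detection p-value under 0.01 on at least 3 of the 12 arrays were kept, which dropped 357 and left 11154. For each of 8639 genes the probe with the highest mean was used, and 2066 genes had more than 1 probe. No genome was used, so no coordinates are given.

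A linear model with a mean for each of the 4 populations was fitted to all 12 arrays, and contrasts were tested with the moderated statistics of limma (lmFit and eBayes), which left 8 residual degrees of freedom and 5.36 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The comparisons were the 6 pairs of populations, the moderated F test over all 4, and the interaction, which is the CD133 difference with CD140 minus the CD133 difference without it. Differences are log2 values with the standard error (SE) of the fit, and group levels are normalized log2 means with SD over 3 arrays. A probe with a detection p-value of 0.01 or more on every array of a population has only a bound there. The fold is then given as "at least", from the mean of the brighter population against the mean, over the dimmer population's arrays, of the higher of the lowest signal among detected probes and the probe's own value. Where only some arrays of a population detected a gene, their number is given. The number of arrays, 3 per population, limits the precision of every value.

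A total of 24 gene lists were fixed before the data were examined, and 20 had at least 5 tested genes: oligodendrocyte progenitor, neural stem cell and radial glia, astrocyte, intermediate progenitor, neuron, glutamatergic neuron, GABAergic neuron, microglia and macrophage, mural cell and fibroblast, erythroid, cell cycle, Notch, Wnt, BMP and TGF-beta, growth factor receptors and ERK feedback, proteoglycan and matrix, cholesterol synthesis, dissociation stress, cytosolic ribosomal protein, and synaptic vesicle and ion channel. The lists for differentiating oligodendrocytes and myelin, endothelial cells, the hedgehog pathway (3 tested genes each) and ependymal cells and choroid plexus (2) were too short for a set test. Lists were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 120 tests of 20 lists in 6 comparisons. Of these, 60 passed. With a correlation estimated from the residuals 9 passed, and the adjusted p under that setting is printed as such. By fry, which tests whether the genes of a list move on balance in 1 direction and compares them with no other genes, 51 passed. Some genes belong to more than 1 list.

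Genes were named by a rule written before the data were examined: PROM1 and PDGFRA, the 5 largest rises and the 5 largest falls, by fitted difference, among called genes that moved the same way in all 3 letters, and the members with the smallest p of each list past the threshold (4 per list, or 2 where more than 5 lists passed). For the interaction, the 5 genes with the smallest p in each direction were taken. Placeholder symbols were passed over. Among called named genes measured by further probes there were 34 pairs of such a probe and a comparison. The further probe gave the same call in 21, the same direction without a call in 11, and the opposite direction in 2.

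The letters recur in all 4 populations and the series design states that each replicate is a separate donor's sample, so a letter was taken as the donor of 4 sorts. As a check, deviations of each array from its population mean were correlated across genes. The 18 pairs of arrays with the same letter in different populations had correlations from -0.0026 to 0.320 with a median of 0.133, and 13 were over 0.1. The 36 pairs with different letters ran from -0.261 to 0.0628 with a median of -0.0704, and 0 were over 0.1. Deviations from a population's own mean sum to 0, so positive same-letter values push the different-letter ones down. The different-letter pairs are therefore no separate evidence, and the check rests on the same-letter values. A fit with the letter as a replicate block was an alternative, printed beside a result where it changes it.

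The model fit and its calls were tested on simulated data, with independent normal noise of each gene's own spread added to normalized gene means. Background correction, normalization, detection, probe choice, donor effects and unequal array quality were not simulated. For CD133-CD140+ against CD133-CD140-, with 8639 genes, 17% of 100 genes changed by 1 log2 unit and 75% of 100 changed by 2 log2 units were recovered, with 6 false calls. Alternatives changed the background correction, the normalization, the filter, the probe rule, the block, array weights, the variance prior and the arrays fitted. The position of CD133+CD140+ cells between the single-positive populations was taken, for each letter, over genes called at least 2-fold different between the single-positive populations in the other letters' arrays. It is the least-squares slope through the origin of the CD133+CD140+ minus CD133-CD140+ difference on the CD133+CD140- minus CD133-CD140+ difference in that letter's own arrays. Both differences subtract the same array, and no value expected without a change was computed. Probes with no gene name here, inside or outside the authors' table, that passed the same filter numbered 4393. They were tested by probe alone, and 18 passed the F test.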

Results

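Gene expression was measured in 4 cell populations sorted from human fetal brain by CD133, a surface protein used to enrich neural stem and progenitor cells, and CD140a, the platelet-derived growth factor receptor alpha carried by oligodendrocyte progenitors. The populations were CD133-CD140-, CD133-CD140+, CD133+CD140- and CD133+CD140+, each with 3 arrays lettered A, B and C for the donors. By its title the series set out to separate multipotent neural progenitors from oligodendrocyte progenitors with this antigen pair. Of 47322 probes, between 10001 (CD133-CD140- replicate C) and 15282 (CD133+CD140- replicate B) were detected per array, with a mean of 11958 ± 2561 (SD, n = 3) in CD133-CD140-, 12047 ± 519 in CD133-CD140+, 14065 ± 1249 in CD133+CD140- and 12202 ± 1498 in CD133+CD140+. Correlations between replicates of a population over the 8639 genes tested ran from 0.888 to 0.969. The leading principal component held 25.1% of the variance and set the CD133-CD140- arrays (-62.3 to -28.2) apart from the other 9 (2.18 to 23.8). The next held 17.3%, with CD133-CD140+ arrays at 12.7 to 37.2 and CD133+CD140- arrays at -40.7 to -18.6, and CD133+CD140+ arrays between them at -1.28 to 8.79.

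The transcripts of the sort antigens were examined before any other gene. PDGFRA (probe ILMN_1681949) was at 8.83 ± 0.85 (normalized log2, SD, n = 3) in CD133-CD140+ and 9.69 ± 0.68 in CD133+CD140+, against 5.27 ± 0.36 in CD133-CD140- and 5.66 ± 0.48 in CD133+CD140-. It was detected on 0 of 3 CD133-CD140- arrays and 1 of 3 CD133+CD140- arrays, so that CD133-CD140+ was at least 5.99-fold and CD133+CD140+ at least 10.9-fold above CD133-CD140- (limma adjusted p = 0.000691 and 0.000437). A further PDGFRA probe, ILMN_2086470, gave the same calls. PROM1 (probe ILMN_1786720) was at 7.30 ± 0.51 in CD133-CD140-, 8.79 ± 0.74 in CD133-CD140+, 9.04 ± 0.46 in CD133+CD140- and 10.25 ± 0.19 in CD133+CD140+. It was higher in CD133+CD140- than in CD133-CD140- by 1.74 ± 0.39 (SE, adjusted p = 0.0279) and in CD133+CD140+ than in CD133-CD140- by 2.96 ± 0.39 (adjusted p = 0.00148). PROM1 transcript did not part the single-positive populations, which differed by 0.25 ± 0.39 (adjusted p = 0.780), and the difference between CD133+CD140+ and CD133-CD140+ of 1.47 ± 0.39 missed the threshold (adjusted p = 0.147). The 1.49 ± 0.39 higher PROM1 in CD133-CD140+ than in CD133-CD140- had an adjusted p of 0.0521, and 0.0320 with the letters as a block.

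**Figure D1:**
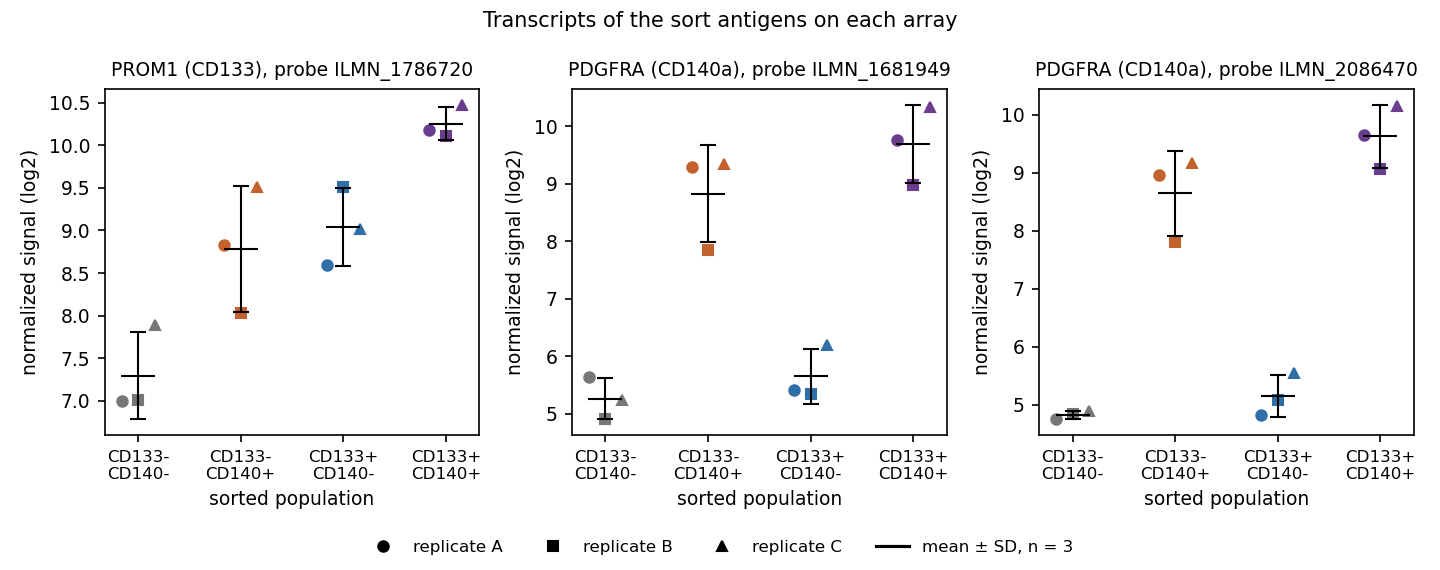
Normalized log2 signal of the PROM1 probe and both PDGFRA probes on each of the 12 arrays (y axes) by sorted population (x axes); symbols are replicates A, B and C, and bars are the mean ± SD of 3 arrays. PDGFRA means lie at 8.83 and 9.69 (ILMN_1681949) in the CD140-positive populations against 5.27 and 5.66 in the others, while PROM1 means in the single-positive populations are 8.79 and 9.04.

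CD133-CD140+ cells were compared with CD133-CD140- cells to ask what distinguishes CD140a-positive cells among those sorted as CD133-negative. Some oligodendrocyte progenitor genes rose with CD140a. APOD, a lipid-binding lipocalin, was at least 7.35-fold higher (fitted log2 difference 4.34 ± 0.45, SE, adjusted p = 0.000182, not detected on any CD133-CD140- array), and OLIG2, a transcription factor of the oligodendrocyte lineage, was 10.6-fold higher (3.41 ± 0.46, adjusted p = 0.00130, detected on 2 of 3 CD133-CD140- arrays). Genes of myeloid cells were also higher. ITGAX, the integrin CD11c, was at least 15.1-fold higher (4.72 ± 0.41, adjusted p = 3.93e-05, not detected in CD133-CD140-), ITGB2, the leukocyte integrin CD18, was 25.6-fold higher (adjusted p = 0.00189, detected on 2 of 3 CD133-CD140- arrays), and the chemokine gene CXCL8 was 42.7-fold higher (5.42 ± 0.62, adjusted p = 0.000343, detected on 1 of 3 CD133-CD140- arrays). Among the falls were hemoglobin genes: the fetal gamma-globin genes HBG1 and HBG2 were 9.24-fold and 7.09-fold lower (adjusted p = 0.00189 and 0.00890), and the alpha-globin genes HBA2 and HBA1 5.75-fold and 5.21-fold lower (adjusted p = 0.00189 and 0.0389, HBA1 detected on 1 of 3 CD133-CD140+ arrays). Probes for HBG1 and HBG2, or for HBA1 and HBA2, target near-identical transcripts, so which copy changed is uncertain.

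By gene list, 10 of 21 oligodendrocyte progenitor genes rose, 0 fell and 11 did not pass in CD133-CD140+ against CD133-CD140- (14 higher and 1 lower adjusted over the list alone, median log2 difference 1.44, camera adjusted p = 2.55e-11). This was adjusted p = 0.0670 with an estimated correlation. The microglia and macrophage list rose in 5 of 7 genes (6 adjusted over the list alone, median 1.93, camera adjusted p = 6.00e-07, adjusted p = 0.0354 with an estimated correlation), among them TYROBP, a signalling adaptor of microglia, at least 1.51-fold, and SPI1, the myeloid transcription factor PU.1, at least 2.47-fold higher (adjusted p = 0.000343 and 0.00189, neither detected in CD133-CD140-). CD83, a surface molecule of activated immune cells, was 19.4-fold higher (adjusted p = 0.000181, detected on 1 of 3 CD133-CD140- arrays). Of 15 dissociation stress genes, 7 rose (11 adjusted over the list alone, median 1.28, camera adjusted p = 2.90e-10, adjusted p = 0.0476 with an estimated correlation), with the growth arrest gene GADD45B 5.81-fold and the transcription factor KLF6 3.71-fold higher (adjusted p = 0.000203 and 0.00189). The erythroid list fell in 5 of 6 genes (6 adjusted over the list alone, median -2.45, camera adjusted p = 3.03e-08). It had adjusted p = 0.0954 with an estimated correlation.

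Neuronal genes were lower in CD133-CD140+ as lists more than as single genes. In the glutamatergic neuron list 2 of 9 fell (7 adjusted over the list alone, median -1.65, camera adjusted p = 7.24e-06, adjusted p = 0.134 with an estimated correlation), namely the cortical transcription factor TBR1, 3.82-fold lower (adjusted p = 0.0102), and NRN1, at least 3.29-fold lower (adjusted p = 0.00189, not detected in CD133-CD140+). In the neuron list 0 of 18 passed (8 lower adjusted over the list alone, median -0.84, camera adjusted p = 3.46e-05). The same test gave adjusted p = 0.129 with an estimated correlation. The proneural gene NEUROG2 was 4.67-fold lower (adjusted p = 0.0242, detected on 2 of 3 CD133-CD140+ arrays), the only call among 5 intermediate progenitor genes (3 adjusted over the list alone, median -1.40, camera adjusted p = 0.00170). These genes had adjusted p = 0.0890 with an estimated correlation. In the radial glia list 2 of 25 rose (4 adjusted over the list alone, camera adjusted p = 0.0120, adjusted p = 0.478 with an estimated correlation), SOX2 by 2.70-fold and NES by 2.87-fold (adjusted p = 0.0136 and 0.0320), while another SOX2 probe, ILMN_1770635, differed by -0.0061 (adjusted p = 0.996). The Notch feedback gene NRARP was 4.17-fold and the ERK feedback inhibitor SPRY1 2.71-fold higher (adjusted p = 0.00509 and 0.0132), with another SPRY1 probe, ILMN_2329914, at 1.55 and adjusted p = 0.0564. With the letters as a block, PPP1R17, MAPT, EGFR and TNR, with differences of -1.40, -1.15, 1.51 and 1.93, went from adjusted p = 0.110, 0.0685, 0.0697 and 0.0545 to 0.0388, 0.0440, 0.0155 and 0.00666. The calls of NEUROG2, SOX2, NES and SPRY1 were lost without some single arrays (limma adjusted p up to 0.102, 0.0698, 0.110 and 0.0550). Those of TBR1, NRN1 and NRARP held without any 1 array. In all, 310 of 8639 genes passed, 211 higher and 99 lower in CD133-CD140+. The count was 168 without CD133-CD140- replicate B, 151 without its replicate C, 169 without CD133-CD140+ replicate A, 151 without its replicate C, 180 with the 6 arrays alone and 188 (82.4% higher against 68.1%) with arrays scaled by their medians.

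CD133+CD140+ cells were compared with CD133+CD140- cells to see the difference with CD140a among CD133-positive cells. Oligodendrocyte progenitor genes were again among the rises. APOD was 17.1-fold higher (4.09 ± 0.45, adjusted p = 0.00197, detected on 1 of 3 CD133+CD140- arrays), the adhesion molecule CNTN1 7.76-fold (2.96 ± 0.52, adjusted p = 0.0220), the NG2 proteoglycan gene CSPG4 7.45-fold (2.90 ± 0.51, adjusted p = 0.0220, detected on 1 of 3) and the collagen gene COL20A1 at least 3.83-fold (adjusted p = 0.00778, not detected in CD133+CD140-). Of 21 genes of that list 12 rose (18 higher and 1 lower adjusted over the list alone, median 1.99, camera adjusted p = 9.30e-30). Camera gave adjusted p = 0.0223 with an estimated correlation. Among synaptic vesicle and ion channel genes 2 of 8 rose (3 adjusted over the list alone, camera adjusted p = 0.000604, adjusted p = 0.0890 with an estimated correlation): the potassium channel gene KCND2, by 3.17 ± 0.65 on the log2 scale (adjusted p = 0.0451, detected on 1 of 3 CD133+CD140- arrays), and the AMPA receptor subunit gene GRIA2, 2.85-fold (adjusted p = 0.0112).

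Globin genes again fell with CD140a. HBG2 was 16.1-fold, HBG1 14.6-fold and HBA2 9.15-fold lower in CD133+CD140+ than in CD133+CD140- (adjusted p = 0.00389, 0.00217 and 0.00206). HBG1 and HBG2 were each detected on 1 of 3 CD133+CD140+ arrays. By list 4 of 6 erythroid genes fell (6 adjusted over the list alone, median -3.02, camera adjusted p = 7.29e-12). The set test gave adjusted p = 0.0674 with an estimated correlation. The lipase gene LIPG was 5.48-fold lower (adjusted p = 0.0409, detected on 1 of 3 CD133+CD140+ arrays), but another LIPG probe, ILMN_1689037, differed by -0.48 (adjusted p = 0.708). In the microglia list 0 of 7 passed, also adjusted over the list alone, with a median of 0.46 (camera adjusted p = 0.00710). This was adjusted p = 0.0980 with an estimated correlation. Cell cycle genes lay lower as a list, with a median of -0.56 (camera adjusted p = 0.000393, adjusted p = 0.134 with an estimated correlation), and 0 of 25 passed, while adjusted over the list alone 2 were lower and 1 was higher. The cyclin D1 gene CCND1 had a fitted difference of 2.19 ± 0.58 with an adjusted p of 0.146, or 0.00707 with the letters as a block. Radial glia genes also lay lower, with a median of -0.49 and 0 of 25 called (5 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.00830). These genes had adjusted p = 0.451 with an estimated correlation. The glutamatergic neuron list (median -0.68, camera adjusted p = 0.0628, adjusted p = 0.534 with an estimated correlation) passed with that block, at 0.0343. In all 52 genes passed, 35 higher and 17 lower. Of the 12 named calls here 5 held without any 1 array, while KCND2, CNTN1, CSPG4, COL20A1, GRIA2, LIPG and HBA1 did not (adjusted p up to 0.225 for KCND2). The count was 100 with 34.0% higher, against 67.3%, when arrays were scaled by their medians, 77.6% were higher with background correction without negative controls, and 111 genes passed with array weights and 11 with the 6 arrays alone. It was 16 without CD133+CD140- replicate A, 7 without its replicate B, 34 without CD133+CD140+ replicate A, 30 without its replicate B, 11 without its replicate C and 34 without CD133-CD140- replicate B, whose arrays enter the shared variance.

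These 2 comparisons share no array, but both come from 1 fit. The variance estimate of each gene and the letters are shared, so the 2 lists of calls are not independent and the chance values below are only a reference. Among genes called in each, 20 were higher with CD140a in both, where independent lists would share 0.855 by chance, and 4 were lower in both, where chance gives 0.195. The 20 included the oligodendrocyte lineage genes OLIG2, SOX10, PDGFRA, CSPG4, APOD, CNTN1, BCAN and COL20A1, of which SOX10 is named after its values were seen, and also ITGAX. PDGFRA encodes the antigen the cells were sorted on, so its rise follows from the sort. In CD133-CD140+ against CD133-CD140- another BCAN probe, ILMN_2246131, differed by 0.25 (limma adjusted p = 0.750). The BCAN call there was lost without some single arrays (adjusted p up to 0.0727). The 4 were HBG1, HBG2, HBA1 and HBA2, near-identical within the gamma and within the alpha pair, so they are not 4 separate signals.

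**Figure D2:**
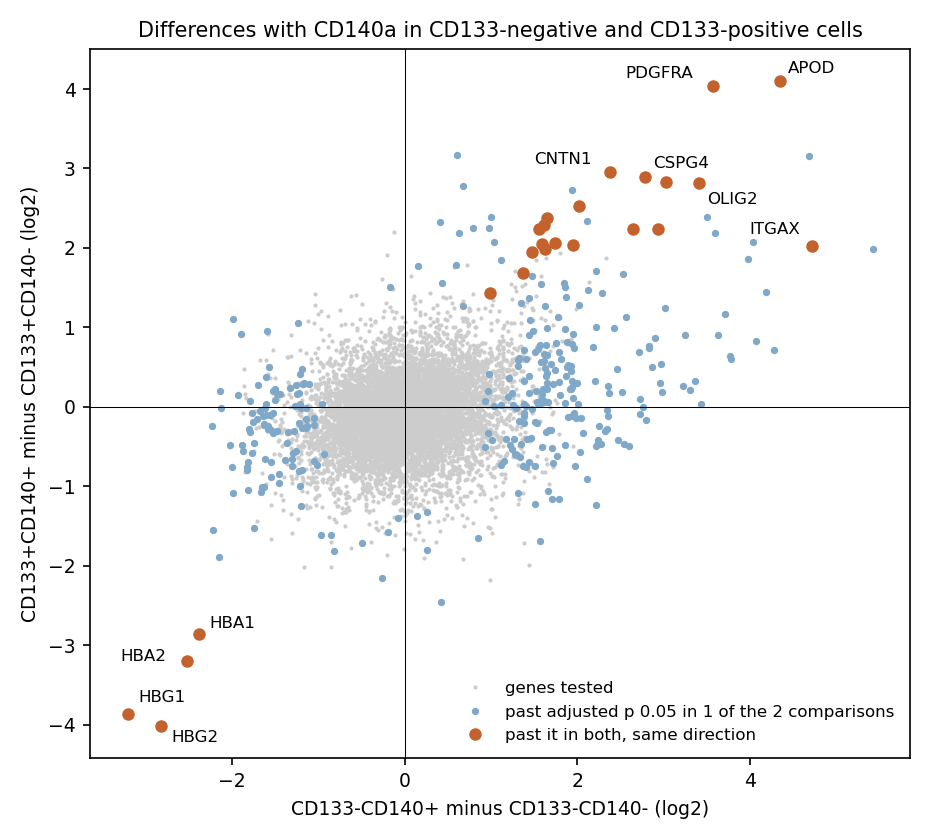
Fitted log2 difference with CD140a among CD133-negative cells (x axis) and among CD133-positive cells (y axis) for 8639 genes; grey points are all genes, blue points passed adjusted p 0.05 in 1 comparison and orange points in both with the same direction. The 20 shared rises lie at the upper right, with APOD at fitted values of 4.34 and 4.09, and the 4 shared falls at the lower left are globin genes (HBG1, -3.21 and -3.87).

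CD133+CD140- cells were compared with CD133-CD140- cells to describe the CD133-positive progenitors. Some genes of the radial glia (8 of 25) and cell cycle lists (9 of 25) rose, and some of the neuron list fell (7 of 18). HOPX, a marker of outer radial glia, was 5.92-fold higher (2.57 ± 0.48, adjusted p = 0.0116, detected on 1 of 3 CD133-CD140- arrays), and NES, an intermediate filament gene of neural stem cells, 4.48-fold (adjusted p = 0.00717, detected on 2 of 3). SOX2 was 3.50-fold higher (adjusted p = 0.00686), while its other probe, ILMN_1770635, differed by 0.35 (adjusted p = 0.776). GFAP was 5.15-fold higher (adjusted p = 0.00710) and LRATD2 6.21-fold (adjusted p = 0.00686), each detected on 1 of 3 CD133-CD140- arrays. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, was 5.56-fold higher (2.47 ± 0.40, adjusted p = 0.00710, detected on 1 of 3), and the spindle checkpoint gene BUB1B at least 2.19-fold higher (adjusted p = 0.00810, not detected in CD133-CD140-). Other large rises were the circadian transcription factor BHLHE40, at least 2.14-fold, and the growth factor binding protein IGFBP4, at least 3.78-fold (adjusted p = 0.00686 and 0.00934, neither detected in CD133-CD140-). Among the falls were SVOP, a synaptic vesicle protein, 6.81-fold lower (-2.77 ± 0.42, adjusted p = 0.00686, detected on 1 of 3 CD133+CD140- arrays), the postsynaptic density gene LRRC7, 6.10-fold lower (adjusted p = 0.0105), ARPP21, 5.31-fold lower (adjusted p = 0.00811), KLHL35, at least 4.18-fold lower (adjusted p = 0.00723, not detected in CD133+CD140-), and TBR1, 5.19-fold lower (adjusted p = 0.00686). Further ARPP21 probes, ILMN_2374728 and ILMN_2289825, differed by -2.40 and -1.28 (adjusted p = 0.00934 and 0.0419).

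Of 25 radial glia genes 8 rose in CD133+CD140- (13 adjusted over the list alone, median 1.05, 25 of 25 positive, camera adjusted p = 8.92e-09). The same test gave adjusted p = 0.126 with an estimated correlation. Of 25 cell cycle genes 9 rose (21 adjusted over the list alone, median 1.29, camera adjusted p = 1.30e-12). These genes had adjusted p = 0.0373 with an estimated correlation. In the neuron list 7 of 18 fell (14 lower and 1 higher adjusted over the list alone, median -1.10, camera adjusted p = 1.57e-11, adjusted p = 0.0523 with an estimated correlation), with STMN2 3.03-fold lower (adjusted p = 0.0288, with another probe, ILMN_1795679, at -1.71 and adjusted p = 0.0739), and 6 of 9 glutamatergic genes fell (8 adjusted over the list alone, median -2.05, camera adjusted p = 1.28e-08). Camera gave adjusted p = 0.0890 with an estimated correlation. Of 8 synaptic vesicle and ion channel genes 2 fell, GRIA2 3.00-fold and the sodium channel gene SCN3A 2.37-fold, detected on 1 of 3 CD133+CD140- arrays and with another probe, ILMN_2283293, at -0.91 and adjusted p = 0.249 (4 adjusted over the list alone, camera adjusted p = 0.000489). The set test gave adjusted p = 0.0890 with an estimated correlation. The SCN3A call was lost under 5 other settings and with each of the 6 arrays left out (limma adjusted p up to 0.173). Notch genes rose in 2 of 12 (6 adjusted over the list alone, camera adjusted p = 0.00325, adjusted p = 0.129 with an estimated correlation), the ligand gene JAG1 2.15-fold and the effector HES1 at least 1.12-fold. The HES1 call was lost under 2 other settings and with each of the 6 arrays left out (limma adjusted p up to 0.149). Those of JAG1 and STMN2 were each lost without 5 single arrays (limma adjusted p up to 0.128). Dissociation stress genes rose here too, in 5 of 15 (11 adjusted over the list alone, median 1.11, camera adjusted p = 1.30e-06, adjusted p = 0.0831 with an estimated correlation), while microglia genes (0 of 7, median -0.036, camera adjusted p = 0.552) and erythroid genes (0 of 6, median -0.18, camera adjusted p = 0.316) did not pass. The Wnt transcription factor gene LEF1 was at least 1.34-fold higher (adjusted p = 0.0434, and 0.0506 with the letters as a block), and SP5 was at least 1.16-fold higher (adjusted p = 0.0683, and 0.0317 with the block). The LEF1 call was lost under 4 other settings, the block among them, and without each of 5 single arrays (limma adjusted p up to 0.173).

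In all, 374 genes differed between CD133+CD140- and CD133-CD140-, 245 higher and 129 lower, and 566 with the letters as a block. Without letter A, B or C, limma called 0 genes each time, against 1450, 1322 and 1185 at an unadjusted p under 0.05. Of the 27 named calls here 13 held without any 1 array. With arrays scaled by their medians 989 passed, 94.2% of them higher against 65.5%, and with array weights 757. The count was 248 without CD133-CD140- replicate A, 119 without its replicate C, and 165, 59 and 105 without CD133+CD140- replicate A, B and C.

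CD133+CD140+ cells were compared with CD133-CD140+ cells, the difference with CD133 among CD140a-positive cells. Of 46 calls 38 were lower in CD133+CD140+, and those that fell in all 3 letters included immune genes. The Fc receptor gene FCGR2A was at least 6.42-fold lower (-3.03 ± 0.25, adjusted p = 0.000127, not detected in CD133+CD140+), while another FCGR2A probe, ILMN_2289849, differed by -1.50 (adjusted p = 0.0429). Also lower were the chemokine gene CCL3L3 9.28-fold (-3.21 ± 0.34, adjusted p = 0.000418, detected on 1 of 3 CD133+CD140+ arrays, with near-identical copies), the cyclooxygenase gene PTGS1 8.71-fold (adjusted p = 0.000430, detected on 1 of 3) and ITGAX 7.21-fold (adjusted p = 0.00462). In the microglia list 2 of 7 fell, TYROBP and SPI1 (4 adjusted over the list alone, median -1.36, camera adjusted p = 2.57e-07). This was adjusted p = 0.0354 with an estimated correlation. Higher in CD133+CD140+ were CSPG5, a brain chondroitin sulfate proteoglycan, 4.20-fold (2.07 ± 0.31, adjusted p = 0.00604), and the transcriptional coregulator CITED1, 4.80-fold (2.26 ± 0.39, adjusted p = 0.0202), each detected on 1 of 3 CD133-CD140+ arrays. So were SEZ6L, 3.48-fold (adjusted p = 0.0438, detected on 2 of 3 CD133-CD140+ arrays), and the growth factor gene BMP7, at least 1.55-fold (adjusted p = 0.0411, detected on 2 of 3 CD133+CD140+ arrays and not in CD133-CD140+). The calls of CITED1, SEZ6L and BMP7 were lost without some single arrays (limma adjusted p up to 0.104, 0.137 and 0.135), while that of CSPG5 held.

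No gene of the oligodendrocyte progenitor list passed between these CD140a-positive populations. The list had a median of 0.71 with 19 of 21 positive (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 9.57e-05). It had adjusted p = 0.175 with an estimated correlation. Cell cycle genes had a median of 0.67 with 24 of 25 positive and 0 calls (4 higher adjusted over the list alone, camera adjusted p = 2.56e-08). The same test gave adjusted p = 0.0666 with an estimated correlation. Glutamatergic genes had a median of -0.95 (0 of 9 called, 4 lower adjusted over the list alone, camera adjusted p = 0.000105, adjusted p = 0.191 with an estimated correlation), and stress genes a median of -0.74 (0 of 15 called, 3 lower adjusted over the list alone, camera adjusted p = 7.76e-05). These genes had adjusted p = 0.107 with an estimated correlation. The 46 calls were 8 higher and 38 lower. The count was 21 without CD133-CD140+ replicate B, 30 without CD133+CD140- replicate C and 7, all lower, with the 6 arrays alone.

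The single-positive populations were compared directly. CD133+CD140- cells had higher cell cycle genes, among them UBE2C, at least 3.54-fold (2.72 ± 0.40, adjusted p = 0.00307, not detected in CD133-CD140+), and the replication licensing gene MCM2, 5.32-fold (adjusted p = 0.0340, detected on 2 of 3 CD133-CD140+ arrays), with 7 of 25 called (21 higher and 1 lower adjusted over the list alone, median 1.21, camera adjusted p = 1.30e-12). Camera gave adjusted p = 0.0373 with an estimated correlation. The MCM2 call was lost with each of the 6 arrays left out (limma adjusted p up to 0.191), while that of UBE2C held. BMP7 was at least 2.71-fold (adjusted p = 0.00152, not detected in CD133-CD140+) and HBG1 8.21-fold higher (adjusted p = 0.00333), and 3 of 6 erythroid genes passed (6 adjusted over the list alone, camera adjusted p = 6.00e-07). The set test gave adjusted p = 0.118 with an estimated correlation. Lower in CD133+CD140- were ITGAX, at least 19.2-fold (-4.87 ± 0.41, adjusted p = 4.15e-05), RGS1, a regulator of G protein signalling in immune cells, at least 12.5-fold (adjusted p = 0.000178), NCKAP1L, an actin regulator of blood cells, at least 10.2-fold (adjusted p = 0.00333), CXCL8, 21.6-fold (adjusted p = 0.00212), and APOD, 12.6-fold (adjusted p = 0.000976, detected on 1 of 3 CD133+CD140- arrays). In the microglia list 4 of 7 fell (6 adjusted over the list alone, median -2.04, camera adjusted p = 6.25e-10, adjusted p = 0.0223 with an estimated correlation), as did 5 of 21 oligodendrocyte progenitor genes (14 adjusted over the list alone, median -1.04, camera adjusted p = 1.41e-14). This was adjusted p = 0.0476 with an estimated correlation. Radial glia genes had a median of 0.64 with 24 of 25 positive and 0 calls (6 adjusted over the list alone, camera adjusted p = 4.90e-05, adjusted p = 0.251 with an estimated correlation); PAX6 was 2.36-fold higher with an adjusted p of 0.0680, or 0.0141 with the letters as a block. The Wnt list (median 0.81, camera adjusted p = 0.0569, adjusted p = 0.204 with an estimated correlation) passed with that block, at 0.0276, and by fry, at 0.0215. In all 149 genes passed, 70 higher and 79 lower. The count was 462 (84.0% higher against 47.0%) with arrays scaled by their medians and 903 (68.5% higher) with array weights, and 93, 85, 71 and 93 without CD133-CD140+ replicate B or C or CD133+CD140- replicate B or C.

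CD133+CD140+ and CD133-CD140- cells differed in 603 genes, 311 higher and 292 lower. Of 21 oligodendrocyte progenitor genes 15 rose and 1 fell (18 and 1 adjusted over the list alone, median 2.08, camera adjusted p = 1.41e-14, adjusted p = 0.0476 with an estimated correlation), with APOD at least 9.99-fold (adjusted p = 0.000437, not detected in CD133-CD140-) and OLIG2 19.1-fold higher (4.25 ± 0.46, adjusted p = 0.000468, detected on 2 of 3 CD133-CD140- arrays). CCND1 was 12.7-fold (3.66 ± 0.58, adjusted p = 0.00338), the epidermal growth factor receptor gene EGFR 6.21-fold (adjusted p = 0.00359, with another probe, ILMN_1696521, at 1.04 and adjusted p = 0.0895), JAG1 2.93-fold (adjusted p = 0.00364) and the Notch effector HES5 3.00-fold higher (adjusted p = 0.00499, detected on 1 of 3 CD133-CD140- arrays). PAOX, a polyamine oxidase gene, was at least 5.84-fold higher (adjusted p = 0.000468), but another PAOX probe, ILMN_2363058, differed by -0.027 (adjusted p = 0.983). Of 25 radial glia genes 7 rose (9 adjusted over the list alone, median 0.43, camera adjusted p = 0.00128). These genes had adjusted p = 0.357 with an estimated correlation.

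Of 9 glutamatergic genes, 8 fell in CD133+CD140+ against CD133-CD140-, also adjusted over the list alone (median -2.43, camera adjusted p = 1.24e-09, adjusted p = 0.0890 with an estimated correlation), NRN1 at least 3.32-fold and TBR1 4.69-fold. Of 18 neuron genes 8 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 2.12e-08, adjusted p = 0.0831 with an estimated correlation), the migrating neuron gene DCX by 3.93-fold (adjusted p = 0.00512). Intermediate progenitor genes fell in 3 of 5 (4 adjusted over the list alone, camera adjusted p = 0.000105, adjusted p = 0.0666 with an estimated correlation), NEUROG2 6.29-fold and EOMES 5.98-fold (adjusted p = 0.00689 and 0.0107, detected on 1 and 2 of 3 CD133+CD140+ arrays). Globin genes fell, HBG1 by 16.4-fold and HBA2 by 10.4-fold (adjusted p = 0.000539 and 0.000468, HBG1 detected on 1 of 3 CD133+CD140+ arrays), in 5 of 6 erythroid genes (6 adjusted over the list alone, camera adjusted p = 3.47e-09). The same test gave adjusted p = 0.0890 with an estimated correlation. Microglia genes had a median of 0.55 and 0 of 7 passed (camera adjusted p = 0.232), and 4 of 15 stress genes rose (5 adjusted over the list alone, camera adjusted p = 0.000156). These genes had adjusted p = 0.118 with an estimated correlation. The count of 603 was 396 without CD133-CD140- replicate B, 335 without its replicate C and 396 without CD133+CD140+ replicate A. It was 219 with the 6 arrays alone, 393 with array weights and 384 (68.5% higher against 51.6%) with arrays scaled by their medians.

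**Figure D3:**
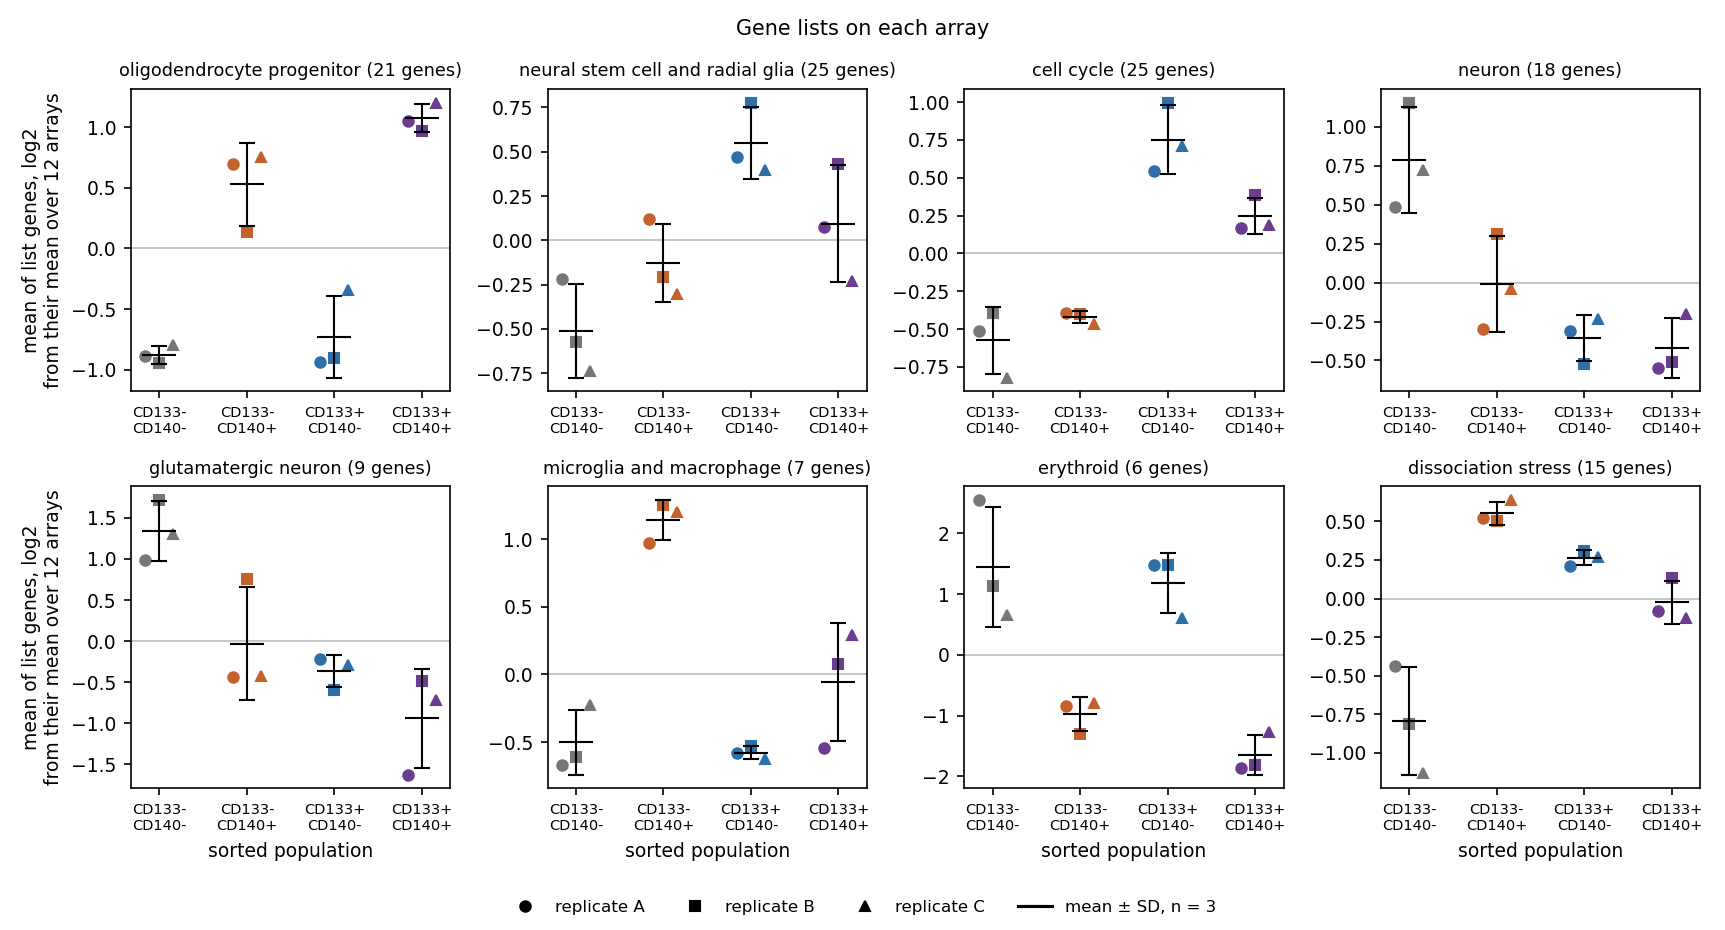
Mean over the tested genes of 8 lists on each of the 12 arrays, as log2 distance from those genes' mean over all arrays (y axes), by sorted population (x axes); symbols are replicates A, B and C and bars the mean ± SD of 3 arrays. The oligodendrocyte progenitor list lies at 0.14 to 1.20 on the 6 CD140-positive arrays and at -0.94 to -0.34 on the others, and the erythroid list at 0.61 to 2.55 on the CD140-negative arrays and -1.86 to -0.79 on the others.

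Across all 4 populations the F test called 595 of 8639 genes. The count was 1093 with array weights, and 326, 323, 308 and 365 without CD133-CD140- replicate B or C or CD133+CD140- replicate B or C. Lists with no set call by camera in any of the 6 comparisons were GABAergic neuron (camera adjusted p from 0.352 to 0.924), BMP and TGF-beta (0.173 to 0.990), cholesterol synthesis (0.538 to 0.916) and cytosolic ribosomal protein genes (0.0912 to 0.759). By fry the BMP and TGF-beta list passed in CD133+CD140- against CD133-CD140- and against CD133-CD140+ (fry adjusted p = 0.0123 and 0.0172). The ribosomal list passed under some other settings, such as no background correction in CD133+CD140- against CD133-CD140+ (adjusted p = 0.0145). The mural cell and fibroblast list passed in CD133-CD140+ against CD133-CD140- alone, at a median of 0.80 with 0 of 7 genes called (camera adjusted p = 0.0320, adjusted p = 0.318 with an estimated correlation), and not in the other 5 (0.107 to 0.918). Of the lists too short for a set test, the myelin list had 1 of 3 genes higher in CD133+CD140+ than in CD133-CD140-, the ependymal list had 1 of 2 higher in CD133+CD140- than in CD133-CD140- and in CD133-CD140+, and the endothelial and hedgehog lists had 0 calls of 3 in each of the 6 comparisons. Growth factor receptor and ERK feedback genes passed in 3 comparisons with the preset correlation and in 0 with an estimated one, with 4 of 13 rising and 1 falling in CD133+CD140+ against CD133-CD140- (7 and 1 adjusted over the list alone, camera adjusted p = 0.000362). Camera gave adjusted p = 0.0523 with an estimated correlation there, and 0.0741 and 0.0937 (0.00229 and 0.0102 with the preset one) in CD133-CD140+ against CD133-CD140- and CD133+CD140+ against CD133+CD140-. Proteoglycan and matrix genes passed against CD133-CD140- in CD133-CD140+, CD133+CD140- and CD133+CD140+ (camera adjusted p = 0.00710, 0.0497 and 0.00517, adjusted p = 0.134, 0.259 and 0.129 with an estimated correlation). In that list COL9A1 was at least 2.33-fold and BCAN at least 3.70-fold higher in CD133+CD140+, though another BCAN probe, ILMN_2246131, differed by 0.93 (adjusted p = 0.120). Astrocyte genes passed against CD133-CD140- in the other populations, with 1, 2 and 2 of 10 genes rising in CD133-CD140+, CD133+CD140- and CD133+CD140+ (camera adjusted p = 0.0117, 0.00471 and 0.0432, adjusted p = 0.251, 0.194 and 0.342 with an estimated correlation).

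Further lists passed with the preset correlation and not with an estimated one. The Notch list rose against CD133-CD140- in 1 of 12 genes in CD133-CD140+ and 4 of 12 in CD133+CD140+ (camera adjusted p = 0.00397 and 0.000153, adjusted p = 0.134 and 0.0890 with an estimated correlation). In CD133+CD140+ against CD133-CD140- 4 of 25 cell cycle genes rose (median 0.73, camera adjusted p = 5.09e-06, adjusted p = 0.0890 with an estimated correlation). Wnt genes lay lower in CD133+CD140+ than in CD133+CD140- (0 of 10 called, median -0.77, camera adjusted p = 0.00434, adjusted p = 0.0937 with an estimated correlation) and higher in CD133+CD140- than in CD133-CD140- (1 of 10 called, median 0.72, camera adjusted p = 0.0365, adjusted p = 0.175 with an estimated correlation). Intermediate progenitor genes, with 0 of 5 called, had medians of -0.89 in CD133+CD140+ against CD133+CD140- and -1.06 in CD133+CD140- against CD133-CD140- (camera adjusted p = 0.0195 and 0.00686, adjusted p = 0.156 and 0.118 with an estimated correlation). Against CD133-CD140+ neuron genes, with 0 of 18 called, had medians of -0.37 in CD133+CD140+ and -0.33 in CD133+CD140- (camera adjusted p = 0.00348 and 0.00152, adjusted p = 0.259 and 0.226 with an estimated correlation). Erythroid genes lay lower in CD133+CD140+ than in CD133-CD140+ (0 of 6 called, median -0.84, camera adjusted p = 0.0185, adjusted p = 0.436 with an estimated correlation). In CD133+CD140- against CD133-CD140+ stress genes had a median of -0.39 (0 of 15 called, camera adjusted p = 0.0259, adjusted p = 0.323 with an estimated correlation) and synaptic genes one of -0.77 (1 of 8 fell, camera adjusted p = 0.00138, adjusted p = 0.0965 with an estimated correlation).

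The CD133 difference depended on CD140 in 47 genes, 5 with a positive and 42 with a negative interaction. GADD45B was higher with CD133 by 2.15 ± 0.27 in CD140-negative cells and differed by -0.86 ± 0.27 in CD140-positive cells (interaction -3.00 ± 0.38, adjusted p = 0.00447). Among CD140-positive cells the endothelin gene EDN1, FCGR2A and the chemokine gene CCL4 fell with CD133 at least 2.03-fold, 6.42-fold and 3.33-fold, and none of them was detected in CD133+CD140+. APBB1IP, an adaptor of integrin activation, fell 7.32-fold there (detected on 1 of 3 CD133+CD140+ arrays). In CD140-negative cells FCGR2A, CCL4 and APBB1IP were detected on no array, and EDN1 on 2 of 3 CD133+CD140- arrays and no CD133-CD140- array, so no fold is given for them there. Their interactions passed (adjusted p = 0.00298, 0.00298, 0.00447 and 0.00421 for EDN1, FCGR2A, CCL4 and APBB1IP), but compare signal with background and measure no size. GRIA2 fell with CD133 by 1.58 ± 0.23 without CD140 and differed by 0.098 ± 0.23 with it (interaction 1.68 ± 0.33, adjusted p = 0.0405). CARMIL3, PHACTR3, RIMKLA and SEMA6D also fell with CD133 without CD140 and had no call with it, with fitted interactions of 2.29, 2.56, 3.08 and 2.21 (adjusted p = 0.0242, 0.0343, 0.0357 and 0.0412). CARMIL3 and SEMA6D were each detected on 2 of 3 CD133-CD140+ and 1 of 3 CD133+CD140- arrays, and RIMKLA on 0 and 2, so the RIMKLA value is no measured size. Dissociation stress genes had a negative interaction in 15 of 15, and 3 passed (9 adjusted over the list alone, median -1.82, camera adjusted p over 20 lists = 1.46e-11). The set test gave adjusted p = 0.0428 with an estimated correlation. With the preset correlation 9 more lists passed, and none of them did with an estimated one. Negative were the microglia list (6 of 7 genes, 1 called, median -1.28, camera adjusted p = 0.00116, adjusted p = 0.102 with an estimated correlation), the radial glia list (23 of 25, median -0.84, camera adjusted p = 4.00e-05, adjusted p = 0.258 with an estimated correlation) and the astrocyte, cell cycle and Wnt lists (camera adjusted p = 0.00456, 0.00279 and 0.0147, adjusted p = 0.228, 0.228 and 0.170 with an estimated correlation). Positive were the neuron list (17 of 18, median 0.74, camera adjusted p = 3.48e-05, adjusted p = 0.170 with an estimated correlation) and the synaptic, glutamatergic and oligodendrocyte progenitor lists (camera adjusted p = 0.00116, 0.00354 and 0.00881, adjusted p = 0.143, 0.350 and 0.378 with an estimated correlation). The count of 47 was 74 with the letters as a block, 87 with arrays scaled by their medians and 30 with the authors' processed values. It was 27 without CD133-CD140- replicate C, 22, 28 and 26 without CD133-CD140+ replicate A, B and C, and 18, 14 and 14 without CD133+CD140- replicate A, B and C.

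Calls with CD133 in CD140-negative and CD140-positive cells, which share no array, had 1 rise and 1 fall in common, BMP7 and SPINT2, against 0.227 and 0.567 by chance (Fisher's exact p = 0.206 and 0.436). These chance values, too, take lists from 1 fit as independent. SPINT2, a protease inhibitor gene, is named after its values were seen. Over all genes, called or not, the CD133 differences in these cells had r = 0.258 and a rank correlation of 0.270, and the CD140a differences with and without CD133 had r = 0.289 and 0.212.

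The place of CD133+CD140+ cells between the single-positive populations was set on a scale where 0 is CD133-CD140+ and 1 is CD133+CD140-. It was 0.758 in letter A over 51 genes, 0.673 in letter B over 15 and 0.460 in letter C over 56, with a mean of 0.630 ± 0.154 (SD, n = 3). Of these genes 30, 14 and 46 were higher in CD133-CD140+, ITGAX and RGS1 among them in each letter, and 21, 1 and 10 in CD133+CD140-, so the place rests mainly on genes of the CD133-CD140+ side, myeloid genes included. The differences from the same CD133-CD140+ array enter both sides of the slope, and its noise can raise the value. With the other letters' differences as weights, which do not carry that noise, the mean was 0.606 ± 0.167; this was chosen after seeing the data. Over genes detected on all 12 arrays it was 0.216 ± 0.385 in the 2 letters that had such genes, with at most 5 genes in a letter. An intermediate place does not hold for every gene list. Oligodendrocyte progenitor list means, as log2 distance from their mean over all arrays, were 0.97 to 1.20 in CD133+CD140+. They were 0.14 to 0.75 in CD133-CD140+ and -0.94 to -0.34 in CD133+CD140-, though no gene of the list passed between the CD140a-positive populations. Cell cycle genes lay between, with median log2 differences of 0.67 from CD133-CD140+ and -0.56 from CD133+CD140-.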

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

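The tests of myeloid lineage genes and of the stress genes against the microglia list were chosen only after the result was seen.

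A difference between groups drew attention to 47 genes, whose CD133 difference depended on CD140 by the interaction test. The 5 with a positive interaction were CARMIL3 (2.29), PHACTR3 (2.56), RIMKLA (3.08), GRIA2 (1.68) and SEMA6D (2.21). The 5 negative ones with the smallest p were EDN1 (-3.45), FCGR2A (-3.12), APBB1IP (-3.39), GADD45B (-3.00) and CCL4 (-2.65). Apart from GADD45B these 5 were not detected in CD133-CD140-, and FCGR2A, APBB1IP and CCL4 not in CD133+CD140- either, so their fitted values, like that of RIMKLA (not detected in CD133-CD140+), compare signal with background and are no measured sizes. Those 5 negative genes passed without any 1 array, and the 5 positive ones did not. Without a whole letter, limma called 0 genes for each of A, B and C, against 793, 767 and 681 at an unadjusted p under 0.05. Of 100 draws of the group labels, the real one included, 1 gave as many genes as the real 47. The highest other gave 35, in a draw that moved labels within letters. The draws moved labels over all populations, so they also broke up the separate CD133 and CD140 differences. They therefore cannot test a dependence on CD140 apart from those differences, and no conclusion on the interaction is drawn from them. They bear only on any difference among the populations. For that F test 1 of 100 gave as many as 595, and the highest other was 38. The genes tested came from the authors' table, whose filter used the real populations. All draws and splits were run on these genes, which can favour the real grouping.

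For each pair of populations the 6 arrays make 10 splits, too few for a share under 0.05, and in each comparison 1 of 10 gave as many genes, the real one. Real counts and the highest of the other splits were 310 and 0, 52 and 0, 374 and 0, 46 and 2, 149 and 0, and 603 and 0, in the order of the comparisons above. The 3 other splits that part as many letter pairs gave 0 by limma in each comparison. At an unadjusted p under 0.05 the highest other splits gave 645, 733, 912, 728, 610 and 850, against 1600, 936, 1823, 900, 1400 and 1938.

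Microglia and macrophage genes were higher in CD133-CD140+ than in CD133-CD140-, with a median of 1.93. Myeloid lineage genes had a median of 1.44 (9 of 10 positive, 5 called), but 7 of these 10 belong to the list in which the pattern was seen. The other 3, the tested part of a wider list of 32 microglia genes, had a median of 0.47 with 0 called, so that microglia or macrophages in the CD133-CD140+ sort cannot be told apart from immune genes switched on in neural cells. The design names no sort against myeloid cells, and their presence stays a hypothesis that may account for part of the 310 calls. Their presence may equally account for part of the 46 calls between the CD140a-positive populations, the 149 between the single-positive ones and the 47 of the interaction. The 52 calls of CD133+CD140+ against CD133+CD140- include ITGAX, so myeloid cells may enter them too, though 0 of 7 microglia list genes passed there. FCGR2A and CCL4 were detected on 3 of 3 CD133-CD140+ arrays and on no array of the other populations. Whether such calls reflect cell content or regulation with CD133 was not tested.

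Globin genes were higher in the CD140a-negative populations, on 6 of 6 such arrays above every CD140a-positive array (means of 8.21 to 10.15 against 5.74 to 6.82), which argues against a single library with many red cells. A wider list of red cell genes other than globins had a median of -0.11 in CD133-CD140- minus CD133-CD140+ (8 of 20 genes tested, 1 called in each direction), with members in both directions. Red cell RNA in the CD140a-negative sorts may still be the source, since abundant globin transcripts could be seen where rarer ones are not, and it cannot be told apart from globin RNA taken up by other cells. No biological explanation was tested.

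Dissociation stress genes were higher against CD133-CD140- in CD133-CD140+, CD133+CD140- and CD133+CD140+ with the preset correlation, and with an estimated correlation in CD133-CD140+ alone (adjusted p = 0.0476, 0.0831 and 0.118). In CD133+CD140- their median was 1.11 (15 of 15 positive, 5 called) while the microglia list was at -0.036, which argues against stress transcripts brought by microglia as the whole source, as far as that rise holds. A difference in handling between the sorts was not tested and stays open.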

How the results depend on the processing

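Weighting the position by the other letters was chosen only after the result was seen. No called named gene, gene list or sort antigen changed direction, but the balance of calls turned over in 3 comparisons. In CD133+CD140+ against CD133+CD140- 35 higher and 17 lower became 34 and 66 with median scaling and 53 and 58 with array weights. In CD133+CD140- against CD133-CD140+ 70 and 79 became 388 and 74 with median scaling, 619 and 284 with array weights, 23 and 12 over genes detected on all 12 arrays, 83 and 79 with the mean of probes, and 110 and 93 with the 2 groups alone. It was even or turned over without CD133-CD140+ replicate A (69 and 69) or CD133+CD140+ replicate C (79 and 76). In CD133+CD140+ against CD133-CD140- 311 and 292 became 323 and 330 with no background correction, 135 and 167 over genes detected on all 12 arrays, 195 and 198 with array weights, and 167 and 168 without CD133-CD140- replicate C. That comparison had the highest count of the 6, but CD133+CD140- against CD133-CD140- had more with median scaling, array weights, the 2 groups alone (445 against 219) and without CD133+CD140+ replicate A (420 against 396) or C (466 against 453), and CD133+CD140- against CD133-CD140+ had more with median scaling and array weights. Among the 130 calls of named genes, 103 passed under every other setting run on all arrays of the comparison, 87 without any 1 array (16 of 23, 5 of 12, 13 of 27, 8 of 12, 13 of 17 and 27 of 29 in the 6 comparisons as ordered in the results and 5 of 10 for the interaction) and 17 without any letter. For the 60 gene list results called, 609 of 689 set tests under other settings passed and 80 did not, and 9 of the 60 passed under all of them (44 of 60 without any letter). Of the 60 not called, 14 passed under at least 1 other setting and 11 without a letter. Counts that moved by more than 1.5 times are given here, and their cause was not tested except where fewer genes or arrays enter by construction. Scaling arrays by their medians gave 188 genes for CD133-CD140+ against CD133-CD140-, 100 for CD133+CD140+ against CD133+CD140-, 989 for CD133+CD140- against CD133-CD140-, 462 for CD133+CD140- against CD133-CD140+, 384 for CD133+CD140+ against CD133-CD140- and 87 for the interaction. It moved the median of all genes to -0.41, 0.55, 0.53, 0.13 and -0.42 in all but the CD133-CD140+ against CD133-CD140- comparison, from -0.10, 0.12, 0.12, 0.023 and -0.078, so directions of calls under it are relative to those shifts. Genes detected on all 12 arrays, 4100 in number, gave 90, 10, 210, 0 (367 at an unadjusted p under 0.05), 35 and 302 in the 6 comparisons in the order above, 12 for the interaction, 268 for the F test and a position of 0.216 ± 0.385 in 2 letters. That position rests on at most 5 genes in a letter, so its place on the other side of the midpoint from 0.630 is uncertain. With median scaling the position was 0.479, also on that side. Array weights gave 111, 757, 903 and 393 for CD133+CD140+ against CD133+CD140-, CD133+CD140- against CD133-CD140-, CD133+CD140- against CD133-CD140+ and CD133+CD140+ against CD133-CD140-, and 1093 for the F test. The replicate block gave 566 for CD133+CD140- against CD133-CD140- and 74 for the interaction, and, within 1.5 times, 431, 73, 56, 177 and 726 for the other comparisons and 813 for the F test. Genes called in both fits were 303 of 310, 52 of 52, 370 of 374, 42 of 46, 138 of 149, 575 of 603 and, for the interaction, 47 of 47. Among named genes and lists it changed the calls given beside their results. The authors' processed values gave 30 for the interaction. The 2 groups compared alone gave 180, 11, 7 and 219 for CD133-CD140+ against CD133-CD140-, CD133+CD140+ against CD133+CD140-, CD133+CD140+ against CD133-CD140+ and CD133+CD140+ against CD133-CD140-. Leaving out letters or arrays of the 2 populations compared gave 38 to 280, 0 to 39, 0 to 283, 0 to 45, 15 to 138 and 101 to 455 genes in the 6 comparisons, 0 to 53 for the interaction and 31 to 595 for the F test, both over all arrays. Arrays of the other populations enter the shared variance, and leaving them out gave up to 353, 57, 466, 44, 155 and 569. By limma the zeros came without a letter: A in CD133+CD140+ against CD133+CD140- (880 at an unadjusted p under 0.05) and against CD133-CD140+ (977), and A, B or C in CD133+CD140- against CD133-CD140- (1450, 1322 and 1185) and the interaction. Without a letter PROM1 in CD133+CD140- against CD133-CD140- differed by 1.36 to 2.05 and passed in none, PDGFRA in CD133+CD140+ against CD133+CD140- by 3.87 to 4.24 and in CD133+CD140- against CD133-CD140+ by -3.52 to -2.82, both not passing without A (adjusted p = 0.122 and 0.0810). With no fold minimum the position was the same, 0.63, because every gene it used was already at least 2-fold different. Signal over background limits genes near the detection threshold, where only a bound is given.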

Other observations

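The tests of outer radial glia genes, of early glial progenitor genes and of YAP targets without pathway components were chosen only after the result was seen.

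A list of 12 outer radial glia genes was higher in CD133+CD140- than in CD133-CD140-, with a median of 1.04, 12 of 12 positive and 4 called (camera p = 3.52e-06, and 0.0479 with an estimated correlation). Of these 8 belong to a fixed list. CD133+CD140- cells may carry more outer radial glia transcripts, a hypothesis found and tested on the same data.

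A list of 10 tested early glial progenitor genes was higher in CD133+CD140+ than in CD133-CD140+, with a median of 0.47, 9 of 10 positive and 0 called by limma (camera p = 0.00277, and 0.0856 with an estimated correlation, fry p = 0.0376). Of these 7 belong to a fixed list. The set result rests on the preset correlation, so that more of such a program in CD133+CD140+ cells is a hypothesis that may not hold.

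A list of YAP targets and pathway components without YAP1 and CCN2 was higher in CD133+CD140- than in CD133-CD140-, with a median of 0.74, 10 of 10 positive and 2 called, CCN1 (1.81 ± 0.26) and WWTR1 (1.22 ± 0.29), with a camera p of 0.00129, and 0.0523 with an estimated correlation. None of them belongs to a fixed list. WWTR1, TEAD1 and LATS1 are pathway components, and the other 7 genes had a median of 0.47 with 7 of 7 positive and 1 called (camera p = 0.00870, and 0.0710 with an estimated correlation). A higher activity of this pathway is a candidate explanation, and CCN1 may also answer to dissociation, which was not tested apart.

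Of 4393 probes with no gene name here, 16, 0, 18, 1, 5 and 43 passed in the 6 comparisons in the order above.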
